A study of Mus musculus with 25 samples.

How the data were processed

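Cells were crosslinked with 1% formaldehyde, libraries were made with the NEBNext Ultra II kit and paired reads of 38 and 37 bp were sequenced on an Illumina NextSeq, per the labels' protocols. Bowtie2, MACS2 and bedtools and the mm10 build (GRCm38) were named per the submitters' processing notes. Their versions and settings, and any control libraries, are not given in the sources used here. Cell line, treatment, antibody and replicate number of all 25 samples were taken from the labels.

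The lists of CTCF, SMC1 and TCF-1 had 3 columns with the position of each peak, so the width of a peak stood in for its strength. The NIPBL and H3K27ac lists had 9 columns, in which the authors gave each peak a score, a fold enrichment, a −log10 p-value and a −log10 q-value. The −log10 q-value that the authors deposited was used only to rank or filter peaks within its own list. The score and the fold enrichment that the authors deposited were not tested. Every −log10 q-value that the authors deposited was above 1. Read totals were not used here, so no interval for counting error was made.

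The comparisons, their tests, the alternatives, 10 gene lists and the rule for named genes were fixed before the data were examined. For each cell line and antibody, peaks of all lists were merged into regions, and an overlap of at least 1 bp placed a region in a list. DN3 TCF-1 sites were merged regions of both TCF-1 lists that both held, and fibroblast TCF-1 sites were the peaks of the single list. Occupancy by TCF-1 was compared with 2-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the 6 comparisons and 95% intervals from 1000 bootstrap draws of 5 Mb blocks. The addition of 0.5 to each cell was made where a cell was 0. Overlaps of TCF-1 sites with other lists were compared with 1000 circular shifts along each chromosome.

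Gene names and positions came from RefSeq genes of GRCm38.p6 (21883 protein-coding genes). All 155 list entries matched, for 149 different genes of which 6 were in more than 1 list. The lists were T lineage regulators, T cell receptor components, Wnt targets, Notch targets, B lineage, myeloid, natural killer and innate lymphoid, fibroblast, cohesin and CTCF, and housekeeping genes. A gene counted when a site or region overlapped its body extended by 10 kb. Each list was tested against all other protein-coding genes and set beside 10000 random lists matched on gene length.

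The annotation used here gave neither strand nor exons and no genome sequence was used here, so 4 parts of the design were adapted. Regions were named by the nearest gene body in place of the nearest transcription start site. No limit was set on the distance, so a region called near a gene may lie beyond 10 kb, up to 182042 bp among the named regions. Distance to either gene end replaced distance to a transcription start site, both within 1 kb and, as an alternative counted as added, within 50 kb. The split into exons and introns and the search for motifs were not run.

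The named genes were Tcf7 and, for each comparison, the genes of up to 10 regions per direction that overlapped TCF-1 and had the highest rank (the lowest of the percentile ranks over the lists that held the region, by −log10 q-value or else by width). Besides these, up to 12 genes of the fixed lists per comparison with such a region were named. A few genes that the rule names are not reported here. Other genes given as examples were chosen after their values were seen. The 10 genes with most TCF-1 sites in each cell line were also chosen after the data were seen.

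Alternatives chosen in advance were an overlap of 50%, a stricter threshold at the median −log10 q-value or width, equal list length, merging across 500 bp, leaving out each list, a replicate block, TCF-1 sites in either list, strata of region width, the comparison with regions in every list, and chromosomes 1 to 19 and X. Equal list length kept the top peaks of each list, as many as the shortest list held. Added after the data were seen were equal list length for gene lists, joint changes, positions, the other splits and the difference between cell lines, leaving out single lists for these and for TCF-1 overlaps, gene lists among genes with a region in any list, and draws of equal numbers of H3K27ac regions.

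Computation used python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and bedtools 2.31.1. Merging with bedtools and with the code used here gave the same 55413 regions for the empty vector CTCF lists, 40103 of them in both. The code was tested on simulated data with 34422 regions, where 400 and 2000 planted regions were all recovered and a planted odds ratio of 13.9 was returned as 13.9. Simulated regions were spaced so that none could merge, so this recovery checks the code only and says nothing about merging of real peaks. With no association planted, 91 of 100 intervals held 1, below the nominal 95%, and 7 of 100 Fisher's exact p-values were under 0.05. The circular shifts called 2 of 20 sets of random sites. Lists of unequal length with no difference planted gave 5337 regions only in the longer and 1 only in the shorter lists, so counts of regions alone do not separate a difference in binding from a difference in depth.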

Results

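TCF-1, the transcription factor encoded by Tcf7, is required for early T cell development, and the study asked how it takes part in the rearrangement of genome folding. Chromatin immunoprecipitation followed by sequencing had been run on 25 samples of 2 mouse cell lines. NIH-3T3, an embryonic fibroblast line, was untreated or induced to express TCF-1 (7 samples). Scid.adh, a thymic lymphoma line that resembles T cell precursors of the DN3 stage, carried an empty vector or a knockout of TCF-1 (18 samples). Antibodies were against CTCF, the protein that bounds chromatin loops, and SMC1, a subunit of the loop-forming cohesin ring. Others were against NIPBL, the loader of cohesin, H3K27ac, an acetylation of active promoters and enhancers, and TCF-1 itself.

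Fibroblast CTCF and every DN3 antibody had 2 lists of peaks per condition, while fibroblast SMC1 had 1 list per condition and fibroblast TCF-1 had 1 list. CTCF lists of untreated fibroblasts held 38369 and 41236 peaks, and those of induced fibroblasts held 68306 and 64645. Fibroblast SMC1 lists held 105033 peaks untreated and 95293 induced, and TCF-1 had 39489 peaks. In DN3 cells, CTCF had 42214 and 53729 peaks with the empty vector and 62353 and 55149 in the knockout, and SMC1 had 70438 and 77587 against 88886 and 96416. NIPBL lists held 9206 and 15232 peaks with the empty vector and 23951 and 14107 in the knockout. H3K27ac lists were of similar length, 38827 and 42180 against 36544 and 37629. DN3 TCF-1 had 4978 and 5356 peaks, of which 3107 merged sites were in both lists. The lists give no read totals, so sequencing depth is unknown, and a region missing from a list is only a region that was not called there.

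**Figure D1:**
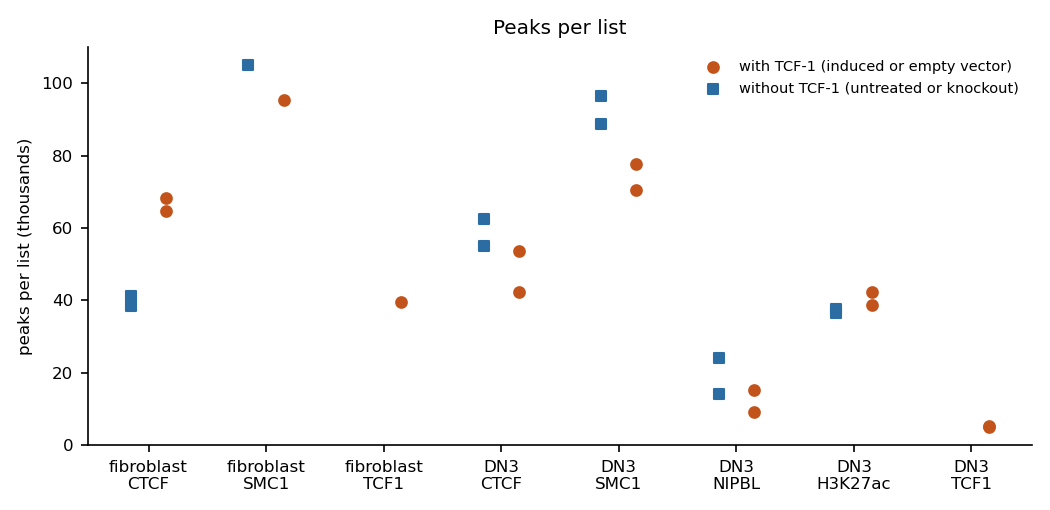
Peaks per list in units of 1000 (vertical axis) for each cell line and antibody (horizontal axis), with circles for samples with TCF-1 and squares for samples without it, each point being 1 list. Fibroblast CTCF lists are longer with TCF-1 (68306 and 64645 against 38369 and 41236), and DN3 SMC1 lists are longer without it (88886 and 96416 against 70438 and 77587).

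Regions "only with TCF-1" were in every list of the condition that has TCF-1 and in no list of the condition that lacks it, and regions "only without TCF-1" were the opposite. All coordinates are on mm10. With 2 lists against 2, only 3 splits of the lists exist, so the smallest 2-sided exact p over these splits is 0.333 and no exact test over them can pass 0.05. Fisher's exact tests therefore compare regions or genes within these lists, and regions are not independent replicates. The lists are not stated to come from separate cultures, so splits measure only the spread between these samples, which may be technical. Fisher's exact p-values and block bootstrap intervals hold no spread between lists at all.

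Tcf7 itself (chromosome 11, 52246527 to 52283383) carried TCF-1 in both lines, with 7 TCF-1 sites within 10 kb of the gene body in induced fibroblasts and 2 in DN3 cells. H3K27ac peaks covered 35.9 and 37.3 kb of this window in the empty vector lists and 36.4 and 36.7 kb in the knockout lists, so the acetylation called at the targeted gene differed by less than the spread between replicates. SMC1 peaks covered 19.8 and 13.0 kb with the empty vector and 24.5 and 19.8 kb in the knockout, and CTCF peaks 2.11 and 2.87 kb against 3.65 and 3.27 kb. CTCF coverage was higher in each knockout list, SMC1 coverage was nearly equal in the closest lists, and the knockout lists of both were longer genome-wide. NIPBL peaks covered 2.87 and 4.81 kb against 9.22 and 3.73 kb, and 2 lists against 2 allowed no exact p under 0.333. TCF-1 lists of knockout or untreated cells were not analysed here, so the absence of the protein is taken from the labels. All TCF-1 sites were thus called in the condition that has TCF-1. Their overlap with regions only with TCF-1 is therefore not separated from other features that lists of that condition share.

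TCF-1 sites in DN3 cells were almost all sites of cohesin and active chromatin. Of the 3107 sites, 98.6% overlapped SMC1 regions found in both empty vector lists, 97.0% overlapped H3K27ac, 72.8% overlapped NIPBL and 45.9% overlapped CTCF, and 36.1% carried all 4. A gene end lay within 1 kb of 67.3% of these sites. The genes with most DN3 sites were Ifi202b, an interferon-inducible gene (7 sites), then Commd1, Esrrg and Midn with 5 each. Alad, a haem synthesis gene, Atp5b and Atp5d, mitochondrial ATP synthase genes, and 1700025G04Rik, Baz2a and Catspere1 had 4 each. Both knockout lists held SMC1 at 98.4% of the sites, H3K27ac at 96.9%, NIPBL at 87.0% and CTCF at 49.6%. Regions in every list of both conditions met 97.4% of the sites for SMC1, 96.2% for H3K27ac, 69.2% for NIPBL and 39.3% for CTCF. After random rotation along each chromosome, the same sites met empty vector SMC1 regions in 3.01%, H3K27ac in 4.88%, NIPBL in 0.5% and CTCF in 1.80% of cases.

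In fibroblasts, 91% of the 39489 induced TCF-1 sites overlapped SMC1 peaks of induced cells, and 83.5% overlapped SMC1 peaks that were called in untreated cells. CTCF regions in both lists met 27.8% of the sites in induced and 19.1% in untreated cells. Gene ends lay within 1 kb of 24.4% of the sites, and the genes with most sites were long ones: Dnm3, which encodes a dynamin, with 42, Rad51b, a DNA repair gene, with 41, Pakap with 37, and Lrmda and Syn3 with 36 each. Next were Zbtb20 with 30, Frmd4a, Lpp and Thada with 29 each, and Foxp1 with 28. Both cell lines shared sites, since 77.8% of DN3 sites overlapped a fibroblast site (1.61% after rotation) and 6.22% of fibroblast sites overlapped a DN3 site (0.130% after rotation). Every overlap given here exceeded all 1000 rotations (permutation test, 1-sided, adjusted p = 0.001, the smallest the rotations can give). Rotation keeps the spacing of sites but not accessibility or mappability.

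T lineage regulators and Wnt targets carried TCF-1 more often than other genes in DN3 cells, while T cell receptor genes did not pass the threshold. Of 18 T lineage regulators, 9 had a DN3 TCF-1 site within 10 kb of the gene body, among them Lef1, the close relative of TCF-1, Bcl11b and Ikzf1, zinc finger factors of T cell commitment, and Myb, a factor of thymocyte growth, against 17.4% of other genes (Fisher's exact test, adjusted p = 0.00858). Wnt targets reached 8 of 15 (exact adjusted p = 0.00858), including Axin2, a feedback inhibitor of the pathway, and Myc, a growth regulator. Housekeeping genes, such as Actb and Gapdh, reached 9 of 14 (exact adjusted p = 0.00128), so the excess in DN3 cells was not restricted to T cell genes. Not past the threshold were T cell receptor genes (5 of 27), Notch targets (4 of 11), cohesin and CTCF genes (4 of 13), B lineage genes (3 of 12), myeloid genes (2 of 12), natural killer and innate lymphoid genes (1 of 11) and fibroblast genes (0 of 22, exact adjusted p = 0.0657).

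In fibroblasts, where 61.6% of all protein-coding genes had a TCF-1 site, all 22 fibroblast genes did (Fisher's exact test, adjusted p = 5.66e-04), among them Col1a1 and Col3a1, collagen genes, with 11 sites each, and Vim, an intermediate filament gene, with 6. Cohesin and CTCF genes reached 13 of 13 (exact adjusted p = 0.0108), with Ctcf itself at 4 sites, and housekeeping genes 13 of 14 (adjusted p = 0.0455). T lineage regulators had sites in 12 of 18, Wnt targets in 12 of 15, T cell receptor genes in 13 of 27, Notch targets in 6 of 11, B lineage genes in 7 of 12, myeloid genes in 6 of 12 and natural killer and innate lymphoid genes in 5 of 11, none past the threshold. Among random lists matched on gene length, the T lineage list in DN3 cells stood at percentile 99.8, Wnt targets at 99.8 and housekeeping genes at 99.99. In fibroblasts the fibroblast list stood at 99.995, cohesin and CTCF genes at 98.9 and housekeeping genes at 99.7.

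CTCF in fibroblasts was called at many more places with TCF-1. There were 15991 regions only with TCF-1 against 38 only without it and 33515 in every list, and TCF-1 overlapped 9.41%, 36.8% (14 regions) and 21.2% of them. Among the strongest regions only with TCF-1 at TCF-1 sites was a region 92985 bp from Irf2bp2, a transcriptional corepressor (chromosome 8, 126686972 to 126688869). Another lay inside Hnrnpa3, an RNA-binding protein gene (chromosome 2, 75657934 to 75659964). Further regions lay inside Prkca, a protein kinase C gene (chromosome 11, 108150397 to 108151871), and near or in Zc3h3, Rbpms, Bicc1, Yif1b, Akr1b8, Adss and Stambp. Genes of the fixed lists with such a region were Ets1, Tcf12 and Zbtb16, lymphoid transcription factor genes with 2 each, and Axin2, B2m, Ccn1, Col1a1, Ebf1, Id3, Nfil3, Notum and Prrx1 with 1 each. Among the strongest regions only without TCF-1 at TCF-1 sites were those near or in Nt5c2, a purine nucleotidase gene (chromosome 19, 46961496 to 46962614), Eef1g, a translation elongation gene, and Nup54, a nuclear pore gene. Others were at Ccdc136, Ptprm, Gabpb1, Rrp36, Vcpip1 and Rnf126.

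The odds of overlapping a TCF-1 site were lower in fibroblast CTCF regions only with TCF-1 than in those only without it (odds ratio 0.178, 95% interval 0.0863 to 0.394, Fisher's exact test, adjusted p = 7.23e-06). Direction turned when each list was limited to its 38369 widest peaks: 1898 regions only with TCF-1 and 1430 only without it then gave an odds ratio of 4.65, and a crossed split of the same lists gave 3.90. Leaving out untreated list 1 or 2 gave 0.357 and 0.329. Gene ends lay within 1 kb of 7.45% of regions only with TCF-1 and 23.7% of those only without it (odds ratio 0.259, Fisher's exact test, adjusted p = 0.00161), and this too turned at equal list length, to 1.71. Cohesin and CTCF genes had a region only with TCF-1 in 11 of 13 cases, among them Nipbl with 4 and Ctcf with 1 (Fisher's exact test, adjusted p = 0.0242), and the adjusted p was 0.450 among genes with a region in any CTCF list. At equal list length the call for these genes was also lost and its direction turned. In the full lists these genes stood at percentile 97.8 among length-matched lists, whose median was 7 genes.

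Cohesin in fibroblasts was called at TCF-1 sites more often among the regions of induced cells. SMC1 had 13926 regions only with TCF-1, of which 20.6% overlapped TCF-1, and 23568 only without it, of which 2.34% did, while 33.0% of the 79630 regions in both lists did. The strongest regions only with TCF-1 at TCF-1 sites included a 13290 bp region near Frmd8 (chromosome 19, 5808310 to 5821599) and 2 in Sipa1l2, a signalling protein gene. Others were in or near Rgma, a guidance molecule gene, Etv6, an ETS family repressor gene (chromosome 6, 134188771 to 134191714), Thada, Aqp2, Agap1, Fbxw11 and Ccbe1. Listed genes with such a region included Znrf3, an antagonist of Wnt signalling, with 2, and Axin2, Bcl11b, Ccn2, Ebf1, Lox, Mau2, Nkd1, Pdgfrb and Rad21 with 1 each. Regions only without TCF-1 at TCF-1 sites lay in or near Lgals3, a galectin gene (chromosome 14, 47383366 to 47386794), and Prrx1, a homeobox gene of mesenchyme. Others were in or near Rpl3, a ribosomal protein gene, Hspa9, a mitochondrial chaperone gene, L3mbtl3, Lrrc74a, Btn2a2, Taf15, Arl4c and Med12l. The distance was 182042 bp for L3mbtl3, 44732 bp for Prrx1, 43237 bp for Arl4c and 24768 bp for Lrrc74a. Listed genes with a region only without TCF-1 at a TCF-1 site included Nipbl, Bcl11b and Znrf3.

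This comparison gave an odds ratio of 10.8 (95% interval 9.86 to 11.9), with a Fisher's exact p smaller than the software can represent, and 3.29 when only peaks at or above the median width of their list were used. SMC1 had 1 list per condition, so the difference has no replicate check. TCF-1 sites were called only in induced cells, so other features shared by lists of induced cells could give the same direction. Against regions in both lists the odds ratio was 0.525. Gene ends lay near 4.14% of regions only with TCF-1 and 3.48% of those only without it (odds ratio 1.2, Fisher's exact test, adjusted p = 0.00140; 1.05 and adjusted p = 0.116 within 5 kb). No fixed gene list passed the threshold for changed SMC1 regions in fibroblasts.

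CTCF in DN3 cells had few regions that were called only with the empty vector. A larger share of those sat at TCF-1 sites and gene ends than of the regions called only in the knockout. Of 320 regions only with TCF-1, 42 overlapped TCF-1 (13.1%), against 53 of 4427 only without it (1.2%) and 3.35% of the 38454 in every list. Counted by site, 42 of the 3107 TCF-1 sites (1.35%) had CTCF only with TCF-1 and 50 (1.61%) only without it. TCF-1 sites thus gained CTCF calls in the knockout about as often as they lost them. Among the 42 regions was a region 95491 bp from Lef1 (chromosome 3, 131014225 to 131014805), at percentile 23.4 by width in its lower list. Its 2 empty vector peaks overlapped only from 131014516 to 131014564. A region inside Nhlrc3 (chromosome 3, 53463203 to 53463868) stood at percentile 83.0. Others lay inside Rab21 and Rab7, endosomal GTPase genes, Timm50, a mitochondrial import gene, and Actr2, an actin nucleation gene. More lay inside Alg3, a glycosylation gene, Ube2j1, a ubiquitin-conjugating enzyme gene, Mia3, a secretory cargo receptor gene, and Mtch2, a mitochondrial carrier gene. Themis, a T cell receptor signalling gene, was the only gene of the fixed lists with such a region. Knockout-only regions at TCF-1 sites lay inside Capsl (chromosome 15, 9463287 to 9464051), Tbce, a tubulin folding gene, and Chtf8, a sister chromatid cohesion gene. The others lay inside Rnf2, a Polycomb gene, Scrib, a cell polarity gene, N6amt1, Gga3, Nudt2, Cep83 and Gm51579.

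The odds ratio of TCF-1 overlap was 12.5 (95% interval 7.67 to 19.1, Fisher's exact test, adjusted p = 1.00e-24). It was 4.71 without empty vector list 2, 5.94 without empty vector list 1 and 7.42 without knockout list 2. Limited to the 42214 widest peaks per list, the comparison held 1245 and 1319 regions and an odds ratio of 3.61, while the crossed split of the same 4 lists gave 0.174, further from 1. A gene end lay within 1 kb of 29.7% of regions only with TCF-1 and 8.72% of regions only without it (odds ratio 4.42, Fisher's exact test, adjusted p = 1.11e-23), and at equal list length the odds ratio was 1.96. No fixed gene list passed the threshold in either direction.

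**Figure D2:**
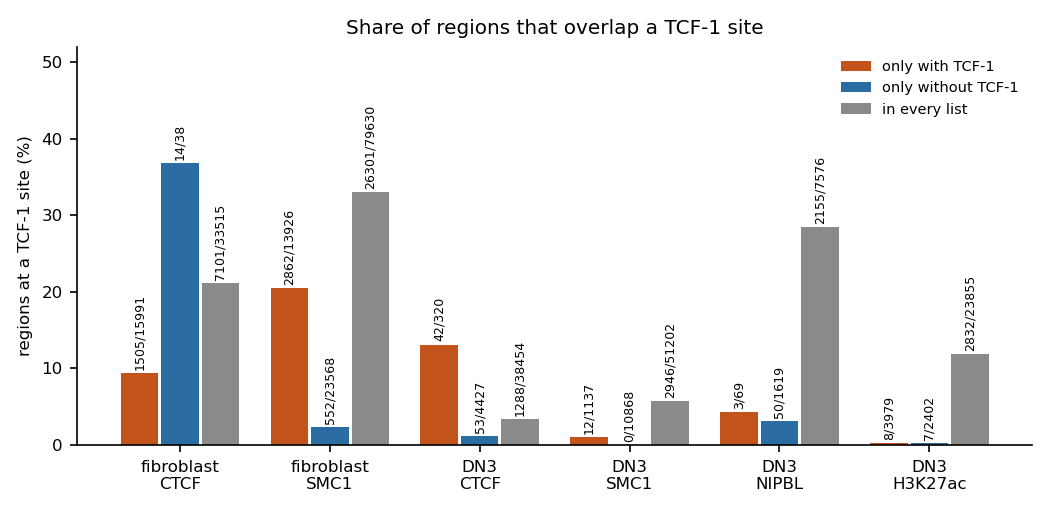
Percent of regions that overlap a TCF-1 site (vertical axis) for each comparison (horizontal axis), with bars for regions only with TCF-1, only without it and in every list, and the counts above each bar. In DN3 CTCF the bars stand at 13.1%, 1.2% and 3.35%, and in fibroblast SMC1 at 20.6%, 2.34% and 33.0%.

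Cohesin regions called only in the knockout surrounded T cell regulator genes. SMC1 had 10868 regions only without TCF-1 against 1137 only with it, and 16 of 18 T lineage regulators had at least 1 of the former, against 24.9% of other genes (Fisher's exact test, adjusted p = 4.01e-07). Lef1 had 15, Runx1, a master factor of blood cells, 11, Bcl11b, Satb1, a chromatin organiser of thymocytes, and Tcf12, an E protein gene, 8 each, and Ikzf1 and Runx3 6 each. Examples within a list were picked after their values were seen. Among genes with a region in any SMC1 list the adjusted p was 1.47e-05. Cohesin and CTCF genes (8 of 13, adjusted p = 0.0372) and housekeeping genes (9 of 14, adjusted p = 0.0212) also passed by Fisher's exact test. Among genes with a region in any list these reached adjusted p of 0.215 and 0.169 by the same test. Cohesin and CTCF genes stood at percentile 95.4 among length-matched lists, whose median was 5 genes. T lineage regulators stood at 100 (median 7) and housekeeping genes at 99.995 (median 3).

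Few SMC1 regions of either kind overlapped TCF-1, 12 of the 1137 only with it and 0 of the 10868 only without it, against 5.75% of the 51202 in every list. The 12 included a 3191 bp region 47886 bp from Rbpj, the nuclear effector of Notch (chromosome 5, 53504702 to 53507892), a region in Lgr5, a Wnt-pathway receptor gene (chromosome 10, 115586233 to 115587117), and a region 3799 bp from Lef1 (chromosome 3, 131105947 to 131106497). Others were in Srebf1, the regulator of lipid synthesis, Agbl3, a tubulin-modifying carboxypeptidase gene, Catspere1 and Ifi202b, with 2 each for the last pair, and near Mndal, an interferon-inducible gene. On chromosome 1 lay 6 of the 12, and those at Mndal, Ifi202b and Catspere1 fell between 173847618 and 177962051. The comparison thus rests in part on this stretch of the genome. The odds ratio was 241 with 0.5 added to each cell (95% interval 87.4 to 457, Fisher's exact test, adjusted p = 9.88e-13) and 62.5 at equal list length, where the other 2 splits gave 0.566 and 1.03. It was 4.28 without empty vector list 2, 15.5 without empty vector list 1, 72.1 without knockout list 1, and 22 or 24.9 without TCF-1 list 1 or 2. The cell of 0 regions stayed at 0 in every bootstrap draw, so the 95% interval holds no uncertainty of that cell. Gene ends lay near 10.4% and 5.31% of the regions only with and only without TCF-1 (odds ratio 2.07, Fisher's exact test, adjusted p = 4.38e-10), with 1.00 and adjusted p = 0.976 without empty vector list 2.

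**Figure D3:**
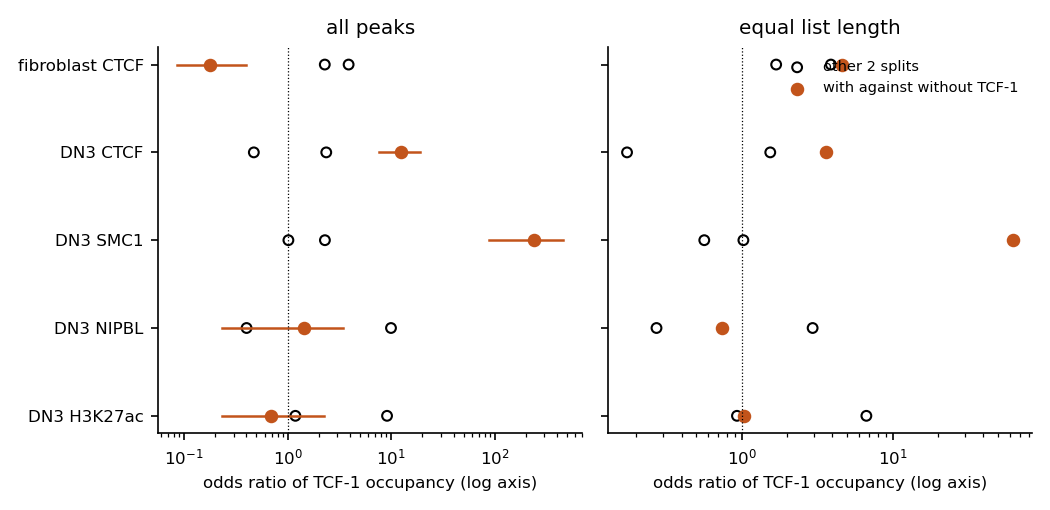
Odds ratio of TCF-1 occupancy (horizontal log axis) for each comparison with 2 lists per condition (vertical axis), with all peaks at left and equal list length at right. Filled points are the split by TCF-1, with lines for its 95% interval at left, and open points are the other 2 splits of the same 4 lists, whose direction from 1 is arbitrary; DN3 SMC1 stands at 241 and 62.5, and at equal list length DN3 CTCF is at 3.61 with another split at 0.174.

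**Figure D4:**
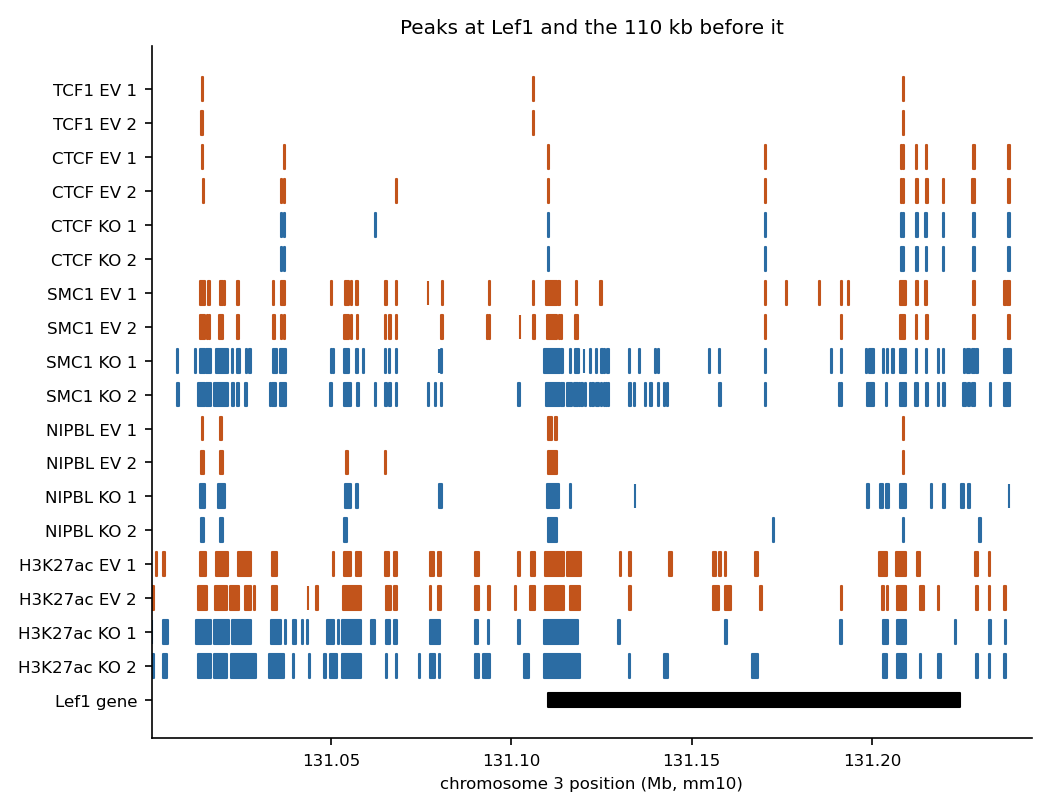
Peaks (bars) of each DN3 list (vertical axis) over Lef1 and the sequence before it (horizontal axis, chromosome 3 position in Mb, mm10), orange for the empty vector (EV) and blue for the knockout (KO). CTCF at 131014225 to 131014805 and SMC1 and H3K27ac over 131105970 are called in both EV lists and in neither KO list. Knockout H3K27ac list 2 has a peak close by (131103627 to 131104932), and knockout SMC1 lists hold additional peaks across the gene. The 2 EV peaks of the CTCF region overlap only from 131014516 to 131014564.

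NIPBL, the cohesin loader, had more regions in both knockout lists alone than in both empty vector lists alone. Knockout list 2 was shorter than empty vector list 2, and that pair had 3145 regions only in the knockout list and 4269 only in the empty vector list. Over all lists, NIPBL had 1619 regions only without TCF-1 and 69 only with it, and 12 of 27 T cell receptor genes had at least 1 of the former (Fisher's exact test, adjusted p = 1.59e-07), as did 8 of 18 T lineage regulators (adjusted p = 2.68e-05), against 5.60% and 5.62% of other genes. Both calls ended at equal list length, where T cell receptor genes had an adjusted p of 0.181 and T lineage regulators of 1 by Fisher's exact test. In the full lists, Fyb, an adaptor of T cell receptor signalling, and Ikzf1 had 4 regions each, and Rag1, the recombinase gene, had 2. At TCF-1 sites, regions only without TCF-1 lay in Sdc4, a syndecan gene (chromosome 2, 164441103 to 164441592), and Impa1, an inositol phosphatase gene. Further ones lay in Slamf1, a lymphocyte receptor gene, Fyb, Iqcg, Ahi1, Ldlrad4 and Scfd2, 11149 bp from Suco and 132875 bp from Lpp. The only 3 regions only with TCF-1 at TCF-1 sites were in Agbl3 (chromosome 6, 34780251 to 34780996) and Srebf1 (chromosome 11, 60210369 to 60210616) and near Bahcc1.

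TCF-1 overlapped 3 of the 69 and 50 of the 1619 NIPBL regions (odds ratio 1.43, 95% interval 0.235 to 3.43, Fisher's exact test, adjusted p = 0.570), and 28.4% of the 7576 in every list. That result rested on single lists, with odds ratios of 0.182 and 0.105 without empty vector list 1 or 2 (Fisher's exact test, adjusted p = 3.82e-09 and 5.36e-13). Without knockout list 1 the odds ratio was 7.10 (Fisher's exact test, adjusted p = 4.29e-18), so no direction is reported for NIPBL. The crossed split of the 4 lists gave 2106 regions, more than the 1688 of the split by TCF-1. A gene end lay near 37.7% and 12% of the regions (odds ratio 4.42, Fisher's exact test, adjusted p = 2.25e-07), which was 2.84 at equal list length and turned to 0.330 without empty vector list 2. NIPBL lists of the same condition shared 50.2% (empty vector) and 48.5% (knockout) of their merged regions, so replicate variation was large.

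H3K27ac differed at many places, mostly away from TCF-1. There were 3979 regions only with TCF-1 and 2402 only without it, and the other 2 splits of the 4 lists gave 993 and 945 in all against 6381. T lineage regulators had regions only with TCF-1 in 8 of 18 cases, against 9.55% of other genes (Fisher's exact test, adjusted p = 0.00239), led by Tox, a factor of thymocyte maturation, with 12, then Runx3 and Satb1 with 3 each and Lef1 with 2. Knockout-only regions were found at 5 of 18 T lineage regulators (exact adjusted p = 0.0333), with 5 at Tcf12 and 2 at Themis, and at 8 of 27 T cell receptor genes (adjusted p = 0.00239), with 2 at Cd8a, a coreceptor gene. Among genes with a region in any H3K27ac list the 3 adjusted p-values were 0.0545, 0.175 and 0.0545 by Fisher's exact test. Among length-matched lists the 3 stood at percentiles 99.9, 96.7 and 99.98, in the same order.

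Only 8 and 7 of these H3K27ac regions overlapped a TCF-1 site. The 8 with TCF-1 were in Agbl3 (chromosome 6, 34780148 to 34781563), Srebf1 (chromosome 11, 60207488 to 60213683), Prdm1, a transcriptional repressor gene of lymphocytes (chromosome 10, 44482865 to 44483870), Lmo7, Lrif1, Smr3a and Grhl2, and 3585 bp from Lef1 (chromosome 3, 131105169 to 131106711). The 7 without it included regions in Pmel, a melanosome gene (chromosome 10, 128715617 to 128717014), and Pigr, the polymeric immunoglobulin receptor gene (chromosome 1, 130837898 to 130839369). The rest were in Gbf1 and 63942 bp from Lpp, 19043 bp from Smyd2, 32155 bp from Dynlt1b and 34236 bp from Cdkal1. The odds ratio was 0.689 (95% interval 0.231 to 2.24, Fisher's exact test, adjusted p = 0.595), and 11.9% of the 23855 regions in every list overlapped TCF-1. Without knockout list 1 or 2 it was 1.51 and 1.94, neither past the threshold. Gene ends lay near 7.79% and 4.87% of the regions (odds ratio 1.65, Fisher's exact test, adjusted p = 7.45e-06; 1.14 and adjusted p = 0.152 without empty vector list 1).

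**Figure D5:**
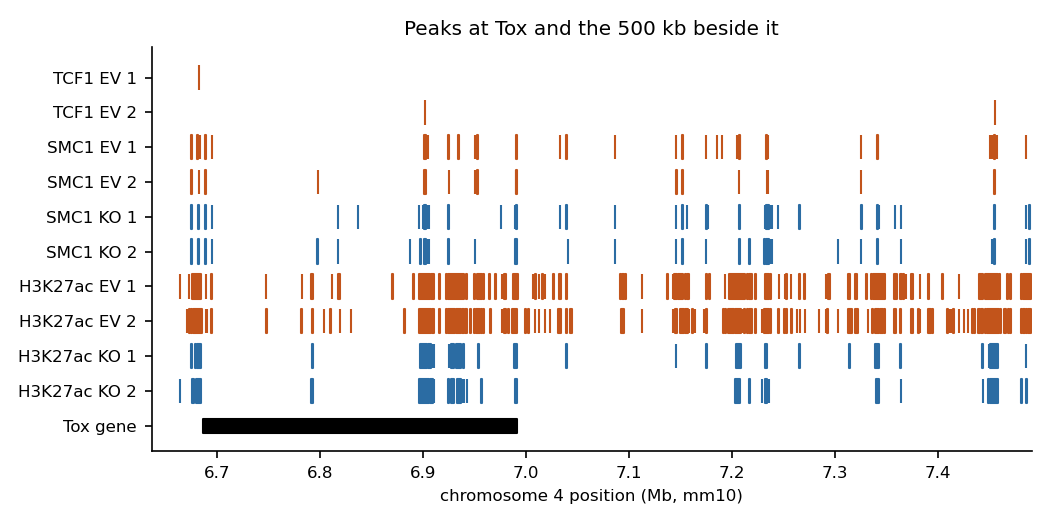
Peaks (bars) of DN3 lists (vertical axis) over Tox and 500 kb beside it (horizontal axis, chromosome 4 position in Mb, mm10), orange for the empty vector (EV) and blue for the knockout (KO). H3K27ac peaks are denser in both EV lists, and 12 regions only with TCF-1 lie within 10 kb of the Tox gene body.

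Where changed regions of 2 factors met in DN3 cells, they mostly had the same direction. CTCF had 320 changed regions only with and 4427 only without TCF-1, and SMC1 had 1137 and 10868. Most of them met no changed region of the other factor, and the odds ratios cover only those that did. Of the CTCF regions only with TCF-1 that met a changed SMC1 region, 31 met an SMC1 region of the same direction and 4 of the opposite, and of those only without TCF-1, 903 and 3 did (odds ratio 2333, Fisher's exact test, adjusted p = 1.93e-49). For SMC1 and H3K27ac the counts were 116 and 16, and 179 and 65 (odds ratio 20, Fisher's exact adjusted p = 1.97e-31). Genes nearest to shared regions only with TCF-1, at any distance, included Atp11b, Nek10 and Prex1. Those nearest to shared regions only without it included Marcks, Myo10 and Id1, an inhibitor of E proteins. The cell cycle gene Ccnd1 was nearest to 2 shared regions only with TCF-1, between 144970758 and 145031220 on chromosome 7, beyond its end at 144939831. Within 10 kb of its body, Ccnd1 had 1 SMC1 region only without TCF-1 and 0 only with it. NIPBL went with SMC1 (9 and 5, 92 and 3, odds ratio 55.2, exact adjusted p = 1.57e-07) and with H3K27ac (25 and 0, 36 and 11, odds ratio 162, adjusted p = 1.84e-10). For CTCF and H3K27ac the counts were 7 and 0, and 14 and 13 (odds ratio 16.1, exact adjusted p = 0.0367), so CTCF regions only without TCF-1 showed no shared direction with H3K27ac, and within 1 kb 25 met the same and 29 the opposite direction. The Agbl3 and Srebf1 regions were only with TCF-1 for SMC1, NIPBL and H3K27ac alike, and that beside Lef1 for SMC1 and H3K27ac. The Srebf1 NIPBL region was weak, at percentile 7.99 in the list where it ranked lowest. Knockout H3K27ac list 2 held a peak next to the Lef1 region (131103627 to 131104932), which merging across 500 bp joins to it. CTCF and NIPBL in DN3 cells (odds ratio 9.46, Fisher's exact test, adjusted p = 0.302) and CTCF and SMC1 in fibroblasts (odds ratio 3.82, adjusted p = 0.337) did not pass. Odds ratios moved with single lists, for CTCF and SMC1 between 63.7 (without empty vector SMC1 list 1) and 1068 (without knockout SMC1 list 1), and for NIPBL and H3K27ac down to 12 without empty vector NIPBL list 1.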

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

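The tests of equal list length for the differences between cell lines and of TCF-1 at the added CTCF regions were chosen after the results were seen, and the criteria that led to a verdict of undecided were made stricter after the values were seen.

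The 2 cell lines differed in how TCF-1 overlap divided the CTCF regions, since the DN3 odds ratio divided by the fibroblast one was 70.0 (95% interval 29.5 to 157, from a bootstrap of genome blocks). At equal list length that ratio was 0.776 (0.465 to 1.34), an interval that includes 1. For SMC1 the ratio was 22.4 (8.35 to 42.2), and 7.43 (3.61 to 12) at equal list length. It rests on 0 of 10868 DN3 regions in a cell, with 0.5 added, and without empty vector list 2 the DN3 odds ratio was 4.28, below the 10.8 of fibroblasts, so the direction of this difference depends on single lists. The classes were also unlike, with 1 SMC1 list per condition in fibroblasts and 2 in DN3 cells. Single pairs of DN3 SMC1 lists gave odds ratios of 6.09 to 13.9, a range that holds the fibroblast value. The odds ratios for a gene end within 1 kb had a ratio of 17.0 for CTCF (6.03 to 33.9), and 1.15 at equal list length (0.818 to 1.62), an interval that includes 1. For SMC1 the ratio was 1.72 (1.33 to 2.16), and 1.47 at equal list length (1.18 to 1.83), though without empty vector list 2 the DN3 value was 1.00, below the 1.2 of fibroblasts. TCF-1 was added in fibroblasts and removed in DN3 cells, so cell line and kind of perturbation are confounded.

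Chromosome Y carried peaks in some knockout lists and in no empty vector list of H3K27ac and NIPBL. H3K27ac had 4 in knockout list 1 and 4 in knockout list 2, at Kdm5d, Uty and Ddx3y, widely expressed genes of the Y chromosome, and near Gm52481. NIPBL had 3 in knockout list 1 and 0 in knockout list 2. Knockout CTCF and SMC1 lists had 0, and the labels do not say whether the knockout cells came from a single clone.

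DN3 CTCF regions only with TCF-1 overlapped TCF-1 more often than those only without it. By site, 42 of the 3107 TCF-1 sites had CTCF only with TCF-1 and 50 only without it. The contrast thus rests on the unequal totals of 320 and 4427 regions. Region width did not account for the difference in share, with a common odds ratio over width quintiles of 9.54 (5.90 to 15.4). Loss of active chromatin in the knockout stays open, since 100% of the 40 such regions with H3K27ac in both empty vector lists had peaks in both knockout lists (91.2 to 100), but so did 99.4% of all 3008 TCF-1 sites with H3K27ac in both empty vector lists, so presence of peaks is saturated and level was not measured. Unequal list length stays open too: at equal length the odds ratio was 3.61, above the bound of 3 set in advance, but its interval of 2.38 to 5.96 includes that bound and another split of the lists lay further from 1. A role of TCF-1 in CTCF binding at these sites remains untested.

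The fibroblast CTCF regions only with TCF-1 far outnumbered those only without it. Binding of TCF-1 at the added regions does not account for most of them in the full lists, since 9.41% overlapped TCF-1 (8.96 to 9.87). At equal list length the share was 26.7%, against 7.27% of regions only without TCF-1. Stronger signal in both induced lists at CTCF sites in general fits, since 81.7% of shared regions away from TCF-1 had wider peaks in both induced lists than in both untreated lists (81.3 to 82.2). The count ratio at equal list length was 1.33, under the bound of 2 set in advance, yet equal lengths force the counts together, so this decides nothing. Depth, antibody yield and a general effect of TCF-1 on CTCF cannot be told apart.

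DN3 H3K27ac regions only with TCF-1 seldom overlapped TCF-1. TCF-1 sites nearby do not account for the direction, since a site within 50 kb was found for 24% of these and 23.2% of regions only without TCF-1 (odds ratio 1.04, 0.862 to 1.26), against 36.6% in every list. Stratified by the density of H3K27ac regions the odds ratio was 1.15, with p = 0.0232 by a Cochran-Mantel-Haenszel test that treats regions as independent (n = 3979 and n = 2402 regions). Its block bootstrap interval included 1 (0.952 to 1.39). This decides nothing, since there was no excess to explain. Indirect effects and differences between the cell populations remain untested.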

How the results depend on the processing

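The tests at either gene end within 50 kb, among genes with a region in any list, and at equal list length or without single lists for gene lists, joint changes and positions were added after the data were seen; the cause of the differences was not tested except where stated. All 84 values of overlap of TCF-1 sites with other lists and 6 of shared TCF-1 sites kept their direction and call. All 66 values of joint changes kept their call, and their direction except CTCF with NIPBL in DN3 cells, which had an odds ratio of 1 at equal list length. Of 78 odds ratios of TCF-1 overlap, 58 kept their call, 3 were stronger and 17 reversed. Of 98 named regions, 95 were kept with an overlap of 50%, 59 at the stricter threshold, 95 at equal list length, 89 with merging across 500 bp and 98 without chromosome Y. Motifs and transcription start sites were not run, fibroblast SMC1 has 1 list per condition and so no replicate block and no value without single lists, and DN3 SMC1 has no value by region width. Depth is unknown and limits every count.

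The stricter threshold removed peaks from every list and lowered most counts, though fibroblast CTCF regions only without TCF-1 numbered 50 against 38. It gave 7239 fibroblast CTCF regions only with TCF-1, 9023 and 13814 SMC1 regions only with and only without it, and in DN3 cells 2235 CTCF regions only without it. DN3 SMC1 had 538 and 5022, NIPBL 36 and 897, and H3K27ac 1639 and 833. The NIPBL odds ratio reversed to 0.0828 and that of H3K27ac to 1.27.

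Equal list length brings the counts of both directions together by construction. It gave 1898 and 1430 fibroblast CTCF regions only with and only without TCF-1, 1245 and 1319 for DN3 CTCF, 2078 and 4163 for SMC1 and 290 and 346 for NIPBL. Odds ratios reversed to 4.65 for fibroblast CTCF, 0.743 for NIPBL and 1.04 for H3K27ac. Gene list calls fell to 0 in fibroblast CTCF, where cohesin and CTCF genes reversed to 0.961, and to 0 in NIPBL. The gene end odds ratio of fibroblast CTCF reversed to 1.71.

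With TCF-1 sites in either list, odds ratios reversed to 0.684 for NIPBL and 1.18 for H3K27ac. Against regions in every list, odds ratios were on the other side of 1 for fibroblast SMC1 (0.525), DN3 SMC1 (0.175) and NIPBL (0.114), and stronger for H3K27ac (0.0150). Gene ends within 5 kb gave 1.05 for fibroblast SMC1.

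Without the extension of genes, TCF-1 odds ratios in DN3 cells reversed to 0.880 for T cell receptor, 0.281 for B lineage and 1.41 for myeloid genes. Calls of lists with changed regions fell to 0 in fibroblast CTCF and 1 in DN3 SMC1, with housekeeping genes at 0.879. Within 50 kb of either gene end, 1 list passed with TCF-1 in fibroblasts, where myeloid genes were at 8.25 and natural killer and innate lymphoid genes at 1.48, and DN3 myeloid genes were at 2.28. Calls with changed regions were then 0 in fibroblast CTCF, 2 in fibroblast SMC1, 5 in DN3 SMC1 and 1 in H3K27ac. Among genes with a region in any list they were 0 in fibroblast CTCF, 1 in DN3 SMC1 and 0 in H3K27ac.

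Leaving out 1 list loosens the criterion, so counts grow by construction. Fibroblast CTCF regions only with TCF-1 ranged from 19283 to 25253 and only without it from 74 to 978. DN3 CTCF ranged from 479 to 3127 and from 5121 to 11771, SMC1 from 1833 to 8384 and from 15263 to 26201, NIPBL from 87 to 1781 and from 1845 to 10493, and H3K27ac from 5083 to 9125 and from 3245 to 6132. Odds ratios ranged from 0.105 to 7.10 for NIPBL (7.10 without knockout list 1, adjusted p = 4.29e-18 by Fisher's exact test) and from 0.399 to 1.94 for H3K27ac. Lists past the threshold with DN3 TCF-1 sites ranged from 3 to 5, with myeloid genes from 1.06 to 2.24 and natural killer and innate lymphoid genes from 0.313 to 1.83. Calls with changed regions ranged from 0 to 1 in fibroblast CTCF, 0 to 2 in DN3 CTCF, 5 to 6 in SMC1 and 3 to 5 in H3K27ac. Gene end odds ratios ranged from 1.14 to 1.84 for H3K27ac, 0.330 to 6.33 for NIPBL and 1.00 to 2.0 for SMC1.

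The samples share only a replicate number, and differences of the same number correlated at 0.00139 for fibroblast CTCF, −0.0391 for DN3 CTCF, 0.0271 for SMC1, 0.0610 for NIPBL and −5.8e-04 for H3K27ac. With the replicate block, the odds ratio of NIPBL was 1.52 and passed the threshold, and no other call differed. That value pools opposite directions. Over regions merged from all 4 NIPBL lists, the lists numbered 1 gave 0.230 and those numbered 2 gave 2.21, so no direction is read from it.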

Other observations

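Some 500 kb bins, chosen after the data were seen, held many H3K27ac regions that differed between empty vector and knockout cells. At least 8 regions only with TCF-1 lay in 77 bins and at least 8 only without it in 29. Tox, a factor of thymocyte maturation, and the stretch beside it without protein-coding genes had 16 and 27 regions only with TCF-1 in neighbouring bins, with 0 only without it. No TCF-1 site of both lists lay in these bins, though around Tox on chromosome 4 TCF-1 list 1 had a single peak (from 6682172) and list 2 had peaks from 6901447 and 7455179. Tox2, a relative of Tox, lay in a bin with 25, the nuclear receptor gene Rora in a bin with 16, Rgs1, Rgs2 and Rgs13, regulators of G protein signalling, in a bin with 15, and St6gal1, a sialyltransferase gene, in a bin with 21. The bin of Apcdd1, an inhibitor of Wnt signalling, had 22, that of Limch1 21 and that of Sema6a, a semaphorin gene, 22. Cd163l1, a scavenger receptor gene of gamma delta T cells, lay among olfactory receptor genes in the bin with most, 32.

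Regions only without TCF-1 were frequent at Btbd9 and Zfand3 (21 in the bin), at Marcks, an actin-regulating kinase substrate gene, and Hdac2, a histone deacetylase gene (18), at Myo10, an unconventional myosin gene (15), at Angpt1, an angiopoietin gene (15), at Hs6st3 (14) and at Mgmt, a DNA repair gene (13). SMC1 regions only without TCF-1 numbered 33 in the bin of Marcks, 29 at Mgmt, 19 at Myo10, 8 at Btbd9, 8 at Hs6st3 and 5 at Angpt1. Bins with many H3K27ac regions only with TCF-1 held them too, with 27 in the bin of Etv5, an ETS factor gene, 18 at Rora and 12 at Cd163l1, while the bin of Sema6a held 4 SMC1 regions only with TCF-1 and 0 only without it. SMC1 regions only without TCF-1 were far more numerous in the genome (10868 against 1137), so these counts say little about a shared direction. Clustering itself was not specific to TCF-1. In draws of 353 regions from each side of each split, 28.3% of regions only with TCF-1 and 29.9% of those only without it shared a bin with another, against 25.9% to 28.6% in the other splits. The lists do not tell an effect of TCF-1 from other differences between the cell populations.

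TCF-1 sites of fibroblasts mostly met cohesin without CTCF, since 53.9% overlapped SMC1 in both conditions and no CTCF present in both lists of a condition. CTCF and SMC1 in both conditions met 18.5%, and 7.21% met neither factor.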
